A study of Homo sapiens with 4 samples.

How the data were processed

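RNA sequencing had been carried out on human primary subcutaneous preadipocytes, taken through 15 days of adipogenic induction into adipocytes and then exposed to the solvent DMSO or to guadecitabine. Guadecitabine is a nucleoside analogue inhibitor of the DNA methyltransferase DNMT1, given at 100 nM. The labels describe the dosing both as 3 times daily and as lasting 3 days, and RNA was collected on day 4. Per the labels' protocols, the libraries were made with a stranded mRNA kit. Samples were grouped by their titles and treatment labels, which gave 2 DMSO and 2 guadecitabine libraries. The guadecitabine columns of the table carried a code name of the drug in place of its name, and were matched to samples by that code and the replicate number. The labels said that treatments were done in duplicate, but not that the duplicates came from separate cultures or donors. The p-values therefore measured the spread between these samples, which may be partly technical.

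Gene expression had been deposited by the authors as RPKM, reads scaled to gene length and to a library total, in 1 table of 25976 genes covering all 4 libraries. The submitters' processing notes named Trimmomatic 0.32, TopHat2 2.1.1, TopHat, Bowtie, DESeq2 1.12.4 and R 3.3.1, with the builds GRCh38.p5 and hg19. The program that counted reads, and whether it used strand, were not given in the sources used here. Chromosome, start and end in the table equalled those of GENCODE 29 on GRCh38 for all 22361 genes with the same versioned gene ID, so coordinates are given as the table lists them, on GRCh38. Spreadsheet dates stood in place of 27 gene symbols, which were restored from GENCODE 29 by gene ID. No columns of sample values were left unused, and no pair of libraries held identical values.

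Depth was read from the steps of the low values. With gene length taken as the merged exons less 1 base per exon, the smallest values mostly fell at whole multiples of what 1 read was worth. The scaling total implied by that step was 20.7 M and 26.6 M reads (M, 1e+06) for DMSO replicates 1 and 2, and 21.0 M and 19.9 M for guadecitabine replicates 1 and 2. Of the values nearest to 1 read, 89.9%, 90.9%, 90.3% and 90.2% lay within 0.01 read of it, in the same order. The RPKM values multiplied by gene length in kilobases summed to 2.97, 3.16, 2.92 and 2.94 M over the matched genes, although reads that are each assigned once to the counted total cannot sum past 1 M. The deposited levels thus stood above the usual RPKM scale. Whether this factor came from the counting or from the scaling total is not given in the sources used here. Ratios between libraries carry this factor only where it differed between them, as it did by a small amount for DMSO replicate 2. A gene with 2 kb of exons and 3 reads would have 0.0726, 0.0565, 0.0713 and 0.0753 RPKM in the 4 libraries, a bound that covers counting error only. Reads could be recovered for part of the genes, so no count model was used.

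Genes with at least 0.5 RPKM in at least 2 libraries were kept, and log2(RPKM + 0.5) was tested with limma 3.58.1 in R 4.3.3. The model had the group as its single term and moderated variances with a mean trend (eBayes). Tests were two-sided with Benjamini-Hochberg adjustment, and an adjusted p under 0.05 counted as a change. Fold changes are guadecitabine minus DMSO on the log2(RPKM + 0.5) scale, which understates changes of genes near 0. Of 29 gene lists, the 27 with at least 5 tested members were tested with camera, with the inter-gene correlation preset to 0.01 and adjustment over the lists, and again with an estimated correlation and with fry. They covered adipocyte identity, fatty acid and cholesterol synthesis, beige adipocytes, oxidative phosphorylation, mitochondrially encoded genes, preadipocytes and fibroblasts, extracellular matrix, smooth muscle, endothelium, macrophages and leukocytes, and bone and cartilage. The others held DNA methylation machinery, nucleoside metabolism, cell cycle, p53 targets, inflammatory and stress responses (unfolded protein and oxidative), steroid metabolism, interferon response, antigen presentation, imprinted and cancer-testis genes, HOX genes, clustered protocadherins, zinc finger genes, histones and ribosomal proteins. Genes below 0.1 RPKM in both libraries of a group and at 1 RPKM or more in both of the other were counted as switched on or off.

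The lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The rule took DNMT1, DNMT3A and DNMT3B, then in each direction the 10 genes furthest from 0 in log2 fold change among those past the threshold with non-overlapping groups and a mean of at least 2 RPKM in the higher group, and 2 members of each list by smallest p. Because no gene passed, the 10 places were filled by the smallest p. Clone-based symbols, symbols on several lines of the table and markers of sex were left out, and 3 genes the rule named are not reported here. Alternatives covered the pseudocount, the filter, the scaling between libraries (quantile, median-of-ratios, TMM), the variance model, the replicate number as a block and each library left out in turn. Removal of a transcript length trend, and the quantile and TMM scalings for gene lists, were added after seeing the data.

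The limma step was tested on simulated data for this comparison with 14377 genes, 200 of them changed, in 10 runs. With gene variances drawn from the fitted prior, 2.6% of genes changed 1.5-fold, 38.4% changed 2-fold, 92.6% changed 4-fold and 99% changed 8-fold were recovered, with 6.6 false calls per run. An earlier version of this simulation used the shrunken variances, in which genes differ too little in variance; it recovered 9.4%, 83.2%, 99.2% and 99.6%, and was replaced after its result was seen. With 1 spread for all genes, the median one between the guadecitabine libraries, 74% and 99.4% were recovered at 1.5-fold and 2-fold, with 20.4 false calls. In a simulated camera run the shifted list was called and 0 of 30 unchanged lists were. The simulated genes varied independently, so this run does not show how camera behaves on lists whose genes vary together. The adipocyte list, for example, had an estimated correlation of 0.96. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.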

Results

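Transcript levels were measured in 4 libraries of human adipocytes differentiated in culture from primary subcutaneous preadipocytes, 2 treated with DMSO and 2 with 100 nM guadecitabine. The series asked what the DNMT1 inhibitor did to gene expression in these cells. Scaling totals ran from 19.9 M to 26.6 M reads (M, 1e+06). At least 1 RPKM was reached by 12814 and 12470 genes in DMSO replicates 1 and 2 and by 12783 and 12718 genes in guadecitabine replicates 1 and 2. The 10 most abundant genes took 13.6% and 18.2% of the summed RPKM in the DMSO libraries and 11.6% and 12.2% in the guadecitabine libraries.

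DNMT1 mRNA, encoding the maintenance DNA methyltransferase that guadecitabine acts on, stood at 25.5 ± 4.06 RPKM in DMSO and 24.9 ± 0.352 RPKM in guadecitabine (SD, n = 2 each). Its log2 fold change was -0.03 with a standard error of 0.15 (limma, adjusted p = 0.954). The drug acts on the protein, so this level does not check the labels. DNMT1 (ENSG00000130816.14) lies on chromosome 19 from 10133345 to 10231286 on GRCh38. DNMT3A, a de novo methyltransferase on chromosome 2 from 25227855 to 25342590, had a log2 fold change of -0.22 with a standard error of 0.16 (adjusted p = 0.585). DNMT3B, the other de novo enzyme, was below the filter in every library, at 0.133 and 0.208 RPKM in DMSO and 0.197 and 0.222 RPKM in guadecitabine. Removing DMSO replicate 1 turned the DNMT1 difference to 0.13, also without a call.

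ATOH8, a basic helix-loop-helix transcription factor, and SUSD2, a membrane protein with a sushi domain, had the smallest p of the 14377 genes tested. ATOH8 (ENSG00000168874.12, chromosome 2 from 85751344 to 85788066) was at 8.32 ± 0.616 RPKM in DMSO and 41.2 ± 1.60 RPKM in guadecitabine (SD, n = 2 each), a log2 fold change of 2.24 with a standard error of 0.12. SUSD2 (ENSG00000099994.10, chromosome 22 from 24181259 to 24189110) was at 6.16 ± 0.128 and 23.7 ± 0.218 RPKM, a log2 fold change of 1.86 with a standard error of 0.12. Both had an adjusted p of 0.0656, short of the threshold, and were the 2 genes that passed with a transcript length trend removed (adjusted p = 0.0294, or 0.0224 with lengths matched by exact gene ID). The log2 fold change furthest from 0 among the genes picked by rule was that of ID1, a helix-loop-helix protein that blocks DNA binding of its partners. ID1 (ENSG00000125968.8, chromosome 20 from 31605283 to 31606515) was at 11.2 ± 5.22 RPKM in DMSO and 86.3 ± 3.83 RPKM in guadecitabine, a log2 fold change of 2.97 with a standard error of 0.31 (adjusted p = 0.155). KISS1, the kisspeptin precursor, had 2.33, MALL, a membrane protein of the MAL family, 1.70 and ALDH1A1, which makes retinoic acid, 1.67 as log2 fold changes. The interleukin receptor gene IL7R had 1.42, the ankyrin repeat gene ANKRD1 1.33 and the secreted glycoprotein gene SCUBE3 1.27. Adjusted p for these 6 genes ran from 0.126 to 0.155. KISS1 was low in DMSO, at 0.194 ± 0.0868 RPKM, against 2.99 ± 0.491 RPKM in guadecitabine. Its ratio of mean RPKM was 15.5, against 7.73 for ID1, so the order of these 2 genes depends on the added 0.5 RPKM.

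On the lower side the smallest p belonged to DPT, the matrix protein dermatopontin. DPT (ENSG00000143196.4, chromosome 1 from 168695459 to 168729264) was at 56.6 ± 2.69 RPKM in DMSO and 21.6 ± 0.484 RPKM in guadecitabine (SD, n = 2 each), a log2 fold change of -1.37 with a standard error of 0.11 (adjusted p = 0.126). PKIB, an inhibitor of protein kinase A, was at 2.43 ± 0.0777 and 0.286 ± 0.0201 RPKM, a log2 fold change of -1.90 with a standard error of 0.17. TNFRSF11B, which encodes osteoprotegerin, was at 242 ± 36.5 and 97.1 ± 1.29 RPKM, a log2 fold change of -1.30. The adhesion receptor gene ADGRD1 and the periplakin gene PPL each had -1.52, INHBE, an inhibin subunit gene, -1.49, and the atypical chemokine receptor gene ACKR4 -1.35. ABCA6, a lipid transporter family gene, had -1.15. None of these 8 passed, with adjusted p from 0.126 to 0.162.

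**Figure D1:**
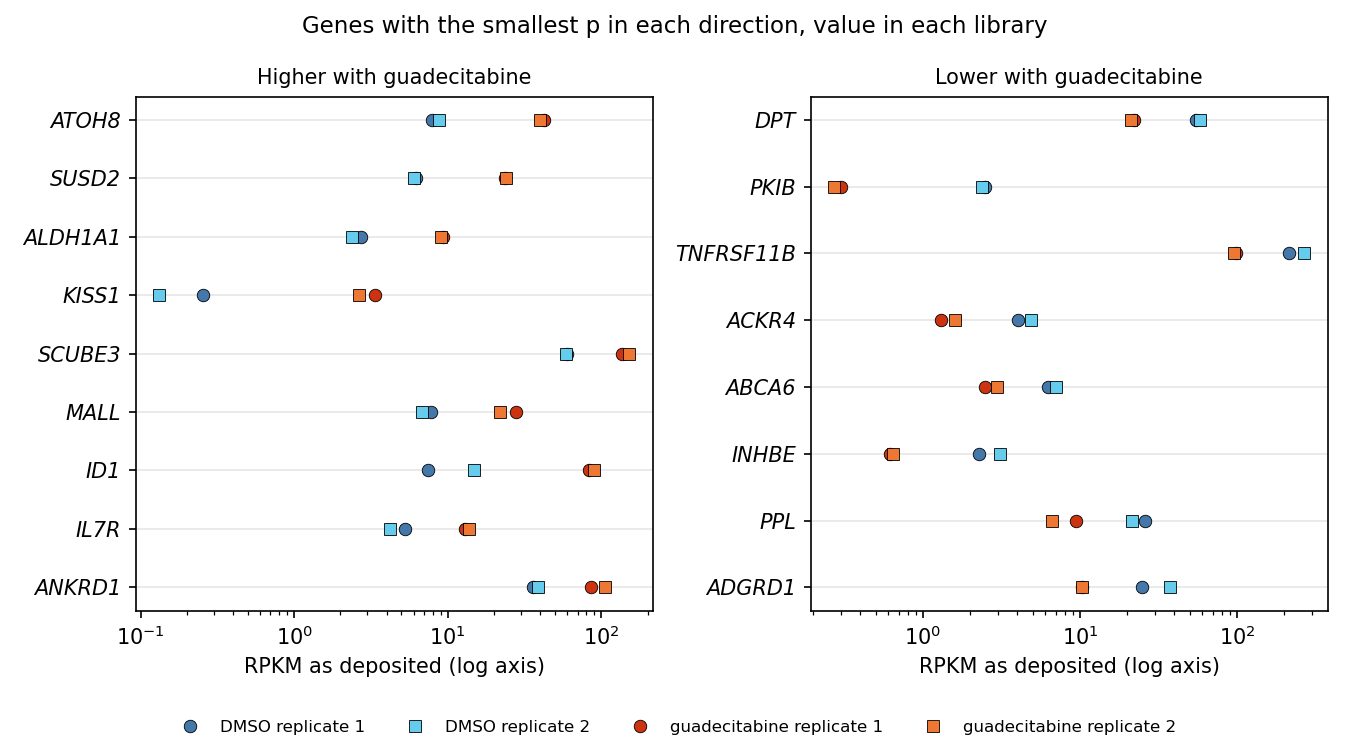
RPKM on a log axis for 9 genes higher and 8 genes lower with guadecitabine, picked by smallest p, 1 point per library, with DMSO in blue and guadecitabine in red and orange. For each gene both guadecitabine libraries lie on the same side of both DMSO libraries, as the rule for naming them required. ATOH8 stands at 7.88 and 8.75 RPKM in DMSO and at 42.3 and 40.0 RPKM in guadecitabine.

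With limma, 0 genes rose and 0 fell at an adjusted p under 0.05, while 1654 genes had an unadjusted p under 0.05, of which 1052 were higher and 602 lower, and 719 would be reached by chance. The higher genes made up 63.6% of these, 53.6% after quantile normalization, 76.5% without DMSO replicate 1 and 45.7% without DMSO replicate 2, where lower genes were the majority. An adjusted p under 0.2 was reached by 68 higher and 15 lower genes. The groups did not overlap for 6950 genes, 48.3% of those tested, where chance gives 33.3%. The DMSO libraries differed from each other by more than 2-fold in 395 genes and the guadecitabine libraries in 92, and the median absolute log2 difference was 0.25 within DMSO and 0.11 within guadecitabine. The first principal component held 63.5% of the variance and set DMSO replicate 2 (37.7) apart from DMSO replicate 1 (-0.99) and guadecitabine replicates 1 (-20.8) and 2 (-15.9). The second held 25.1% and set DMSO replicate 1 (-24.9) apart from DMSO replicate 2 (7.62) and guadecitabine replicates 1 (7.48) and 2 (9.84).

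The count of calls rested on which DMSO library was used. Without DMSO replicate 1, 3466 genes rose and 876 fell, and without DMSO replicate 2, 295 rose and 245 fell, in fits that take the lone DMSO library to vary like the guadecitabine pair. In both of these fits 244 genes rose and 99 fell, ATOH8, SUSD2, ID1, DPT, PKIB and the other genes picked by smallest p among them, and 19 and 3 genes were called in opposite directions. Independent lists would share 71.1 and 14.9 genes, but the fits share the guadecitabine libraries, so part of the excess may come from these. The genes picked by smallest p came from these same libraries and had to differ from both DMSO libraries in 1 direction. Their calls in both fits were thus favoured in advance and add no separate support. Among them, ID1 had log2 fold changes of 2.50 without DMSO replicate 1 and 3.44 without DMSO replicate 2. Without either guadecitabine library 0 genes were called.

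Adipocyte genes were the group in which the DMSO libraries stood furthest apart. The list of adipocyte identity and lipid droplet genes had a median log2 fold change of 1.01, with 19 of 20 tested members positive (camera, adjusted p = 0.00196, and adjusted p = 0.890 with an estimated correlation). No member changed over all genes or adjusted over the list alone. ADIRF, a gene of adipogenesis, was at 33.2 ± 14.4 RPKM in DMSO and 68.5 ± 9.82 RPKM in guadecitabine (SD, n = 2 each), and CEBPA, an adipogenic transcription factor, at 2.79 ± 2.51 and 7.90 ± 1.75 RPKM. Their log2 fold changes, 1.09 and 1.59, were 0.65 and 0.72 without DMSO replicate 2 and 1.54 and 2.45 without DMSO replicate 1. All 20 members were lowest in DMSO replicate 2, by a median of -1.62 against DMSO replicate 1, and 15 by more than 2-fold. FABP4, the fatty acid binding protein of adipocytes, chosen after its values were seen, had 280 and 16.4 RPKM in the DMSO libraries and 220 and 377 RPKM in the guadecitabine libraries. Against DMSO replicate 1 alone the list's median was 0.06 (adjusted p = 0.553), and against DMSO replicate 2 alone it was 1.80.

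**Figure D2:**
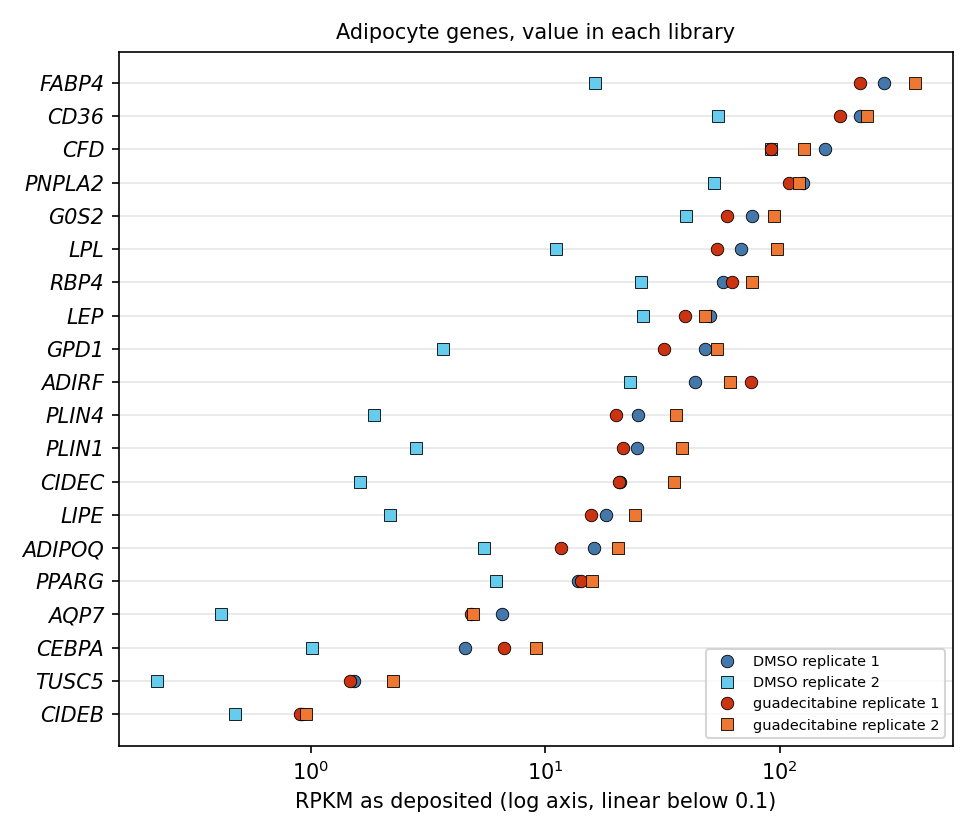
RPKM of the 20 tested adipocyte genes, 1 point per library, on an axis that is logarithmic above 0.1 and linear below. DMSO replicate 2, drawn as light blue squares, is the lowest library for all 20 genes, while DMSO replicate 1 lies near the guadecitabine libraries, as for FABP4 at 280 RPKM against 220 and 377 RPKM.

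Genes of oxidative phosphorylation were higher in guadecitabine, with a median log2 fold change of 0.34 and all 35 members positive (camera, adjusted p = 7.4e-08, and adjusted p = 0.890 with an estimated correlation). The respiratory chain genes NDUFA4 and COX7A2 had log2 fold changes of 0.54 and 0.49, and no member changed over all genes or adjusted over the list alone. These genes were also lower in DMSO replicate 2 than in DMSO replicate 1, by a median of -0.36, and 34 of them were lowest there. The median was 0.18 without DMSO replicate 2, 0.54 without DMSO replicate 1 and 0.19 after quantile normalization, each past the threshold. The 20 tested mitochondrially encoded genes had a median of -0.17 (camera, adjusted p = 0.00218, and adjusted p = 0.890 with an estimated correlation), with an SD of 0.68 between members. No member changed over all genes or adjusted over the list alone. The list was not limited to protein-coding genes, as MT-TT and MT-TM, transfer RNA genes below the filter, were on it. MT-ND5 had -0.52 and MT-ND4L -0.49 (-0.53 and -0.49 without DMSO replicate 1, -0.51 and -0.48 without DMSO replicate 2). The list's median was -0.43 in DMSO replicate 2 against DMSO replicate 1. Without DMSO replicate 1 it was 0.10, with the test still pointing down but not past the threshold (adjusted p = 0.332), without DMSO replicate 2 it was -0.36, without guadecitabine replicate 2 it was -0.04 and after quantile normalization -0.28.

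Lipid synthesis lists did not pass. Cholesterol synthesis genes had a median of 0.27 with all 22 positive (camera, adjusted p = 0.0515, and adjusted p = 0.946 with an estimated correlation), led by NSDHL at 0.47 and FDFT1 at 0.40 (0.18 and 0.13 without DMSO replicate 2, 0.76 and 0.67 without DMSO replicate 1). All 22 were lowest in DMSO replicate 2, and without that library the median was -0.14 (adjusted p = 0.0863). The list passed as higher after quantile (adjusted p = 0.0344), median-of-ratios (0.0205) and TMM scaling (0.0193), without DMSO replicate 1 (median 0.66, 7.0e-08) and without guadecitabine replicate 1 (0.34, 0.00616). With a transcript length trend removed its adjusted p was 0.0313, or 0.0853 with lengths matched by exact gene ID. Fatty acid and triglyceride genes had a median of 0.19 (adjusted p = 0.840), with ACACA at -0.23 and ACLY at 0.22 (0.10 without DMSO replicate 2, 0.34 without DMSO replicate 1), and its call went both ways: lower without DMSO replicate 2 (-0.17, adjusted p = 0.0180) and higher without DMSO replicate 1 (0.51, adjusted p = 0.00647). Of these 2 lists, no member changed over all genes or adjusted over the list alone. Beige adipocyte genes had a median of 0.14 over 8 tested members (adjusted p = 0.852). In that list DIO2, the thyroid hormone activating deiodinase, and ELOVL3, a fatty acid elongase, rose adjusted over the list alone, and 0 over all genes. DIO2 was at 0.119 ± 0.0210 RPKM in DMSO and 1.26 ± 0.224 RPKM in guadecitabine, and ELOVL3 had a log2 fold change of 0.86. Without DMSO replicate 2 the list's median was -0.14. Steroid hormone genes had a median of 0.31 (adjusted p = 0.126), with HSD11B1, which regenerates cortisol, at 0.82 and HSD17B11 at 0.44 and no change over all genes or adjusted over the list alone. Without DMSO replicate 2 the steroid median was 0.08 (adjusted p = 0.788).

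Extracellular matrix genes were lower in guadecitabine, with a median log2 fold change of -0.29 and 1 of 24 members positive (camera, adjusted p = 2.4e-07, and adjusted p = 0.890 with an estimated correlation). COL15A1, a basement membrane collagen, was at 92.6 ± 15.7 RPKM in DMSO and 46.1 ± 5.78 RPKM in guadecitabine (SD, n = 2 each), a log2 fold change of -0.99, and was the 1 member that fell adjusted over the list alone, against 0 over all genes. COL3A1, a fibrillar collagen, had -0.73. These genes were higher in DMSO replicate 2 than in DMSO replicate 1 by a median of 0.34, and without DMSO replicate 2 the list's median was -0.19 (adjusted p = 0.0302). Preadipocyte and fibroblast genes had a median of 0.15 (adjusted p = 0.883) with 10 of 18 positive, and GREM1, a secreted antagonist of bone morphogenetic proteins, rose adjusted over the list alone, with 0 over all genes. GREM1 read 605 and 490 RPKM in DMSO and 964 and 991 RPKM in guadecitabine, a log2 fold change of 0.84, and the endoglin gene ENG had 1.04 (0.68 without DMSO replicate 2). DMSO replicate 2 differed from DMSO replicate 1 by a median of -0.18 in these genes.

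Among markers of other cell types, smooth muscle and myofibroblast genes had a median of 0.35 with 14 of 17 positive (camera, adjusted p = 0.0319, and adjusted p = 0.890 with an estimated correlation). Within the list MYH11, smooth muscle myosin, fell adjusted over the list alone with a log2 fold change of -0.83, against the list's direction, CSPG4, a pericyte proteoglycan, had 0.57, and 0 members changed over all genes. The list was lower in DMSO replicate 2 by a median of -0.46, and its call ended without DMSO replicate 2 (0.11, adjusted p = 0.206) and without guadecitabine replicate 2 (0.32, adjusted p = 0.118). The median was 0.53 without DMSO replicate 1 and 0.21 after quantile normalization. Bone and cartilage genes had a median of 0.30 (adjusted p = 0.126), in which the cartilage proteoglycan gene ACAN at 2.34 and the alkaline phosphatase gene ALPL at 0.69 rose adjusted over the list alone, and 0 over all genes. The bone and cartilage list passed without DMSO replicate 2 (0.32, adjusted p = 0.0180) and without guadecitabine replicate 1 (0.42, adjusted p = 0.0102), but not without DMSO replicate 1 (0.38, adjusted p = 0.405) or guadecitabine replicate 2 (0.20, adjusted p = 0.360). ACAN had 1.34 without DMSO replicate 2, and read 24.5 and 5.70 RPKM in the DMSO libraries and 56.5 and 69.5 RPKM in the guadecitabine libraries. Of 5 tested endothelial genes (median 0.15, adjusted p = 0.852), 0 changed over all genes, and another 9 were below the filter. EMCN, an endothelial sialomucin gene, rose adjusted over the list alone with 1.70 (2.23 without DMSO replicate 1, 1.17 without DMSO replicate 2). It read 0.613 and 0.0341 RPKM in the DMSO libraries and 2.50 and 1.59 RPKM in the guadecitabine libraries. PECAM1 had -0.35 (-0.12 without DMSO replicate 1, -0.57 without DMSO replicate 2). Only 4 macrophage and leukocyte genes were tested, too few for camera, with CD68 at 0.48 and FCER1G at 0.39 (0.29 and 0.06 without DMSO replicate 2, 0.67 and 0.72 without DMSO replicate 1) and no change over all genes or adjusted over the list alone. Their median was -0.52 in DMSO replicate 2 against DMSO replicate 1, and that of the endothelial genes -0.45. Against DMSO replicate 2 alone the endothelial list's median was 0.40, and against DMSO replicate 1 alone it was -8.0e-04.

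Genes of the unfolded protein and integrated stress response were lower in guadecitabine, with a median of -0.23 and 8 of 22 members positive (camera, adjusted p = 0.00196, and adjusted p = 0.890 with an estimated correlation). Adjusted over the list alone, 1 rose and 5 fell, and 0 changed over all genes. DDIT4, a stress-induced inhibitor of mTOR signalling, was at 352 ± 20.9 RPKM in DMSO and 192 ± 14.7 RPKM in guadecitabine (SD, n = 2 each), a log2 fold change of -0.87. DDIT3, the transcription factor CHOP, had -0.62 and was at 46.3 ± 0.183 and 29.9 ± 1.45 RPKM. Chosen after their values were seen, CHAC1, PSAT1 and TRIB3 had -0.68, -0.67 and -0.89, and CALR, the chaperone calreticulin, was the member that rose, with 0.56. DMSO replicate 2 differed from DMSO replicate 1 by a median of 0.11. Without DMSO replicate 2 the median was -0.25 and the call ended (adjusted p = 0.0760), and after quantile normalization it was -0.38.

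Oxidative stress and metallothionein genes had a median of 0.32 (adjusted p = 0.126), with 0.11 without DMSO replicate 2 and 0.45 without DMSO replicate 1, neither past the threshold. Adjusted over the list alone, 4 rose and 2 fell, and 0 changed over all genes. MT1E, a metal-binding metallothionein with close paralogs among which reads can be split, had 0.57, and SOD2, the mitochondrial superoxide dismutase, -1.27 (-0.80 without DMSO replicate 2). SOD2 read 109 and 212 RPKM in the DMSO libraries and 63.8 and 61.5 RPKM in the guadecitabine libraries. Inflammatory cytokine and adipokine genes had a median of 0.19 (adjusted p = 0.852), and adjusted over the list alone 1 rose and 1 fell, with 0 over all genes. The chemokine CCL2 fell there with -0.97, from 120 ± 4.36 to 61.2 ± 9.33 RPKM, and the chemokine CXCL5 rose with 1.00. The list of p53 targets had a median of 0.05 (adjusted p = 0.883), which turned to -0.02 after quantile, median-of-ratios and TMM scaling alike, with CYFIP2 at 0.69 and SESN2 at -0.52 and no change over all genes or adjusted over the list alone.

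Cell cycle genes were higher in guadecitabine, with a median of 0.27 and 26 of 32 positive (camera, adjusted p = 0.00508, and adjusted p = 0.890 with an estimated correlation). TK1, thymidine kinase, was at 10.7 ± 1.88 RPKM in DMSO and 23.4 ± 6.49 RPKM in guadecitabine (SD, n = 2 each), and FOXM1, a transcription factor of the cell cycle, at 9.64 ± 1.79 and 16.8 ± 2.85 RPKM. No member changed over all genes or adjusted over the list alone. DMSO replicate 2 stood above DMSO replicate 1 by a median of 0.47. The median was 0.45 without DMSO replicate 2, and 0.11 without DMSO replicate 1, where the test pointed the other way (adjusted p = 0.481). The call also ended without guadecitabine replicate 1 (0.14, adjusted p = 0.0725), and the median was 0.14 with a transcript length trend removed (adjusted p = 0.0455, or 0.0618 with lengths matched by exact gene ID).

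DNA methylation and demethylation genes had a median of -0.11 (camera, adjusted p = 0.0746), with TET3, a methylcytosine dioxygenase, at -0.70 and MBD2, a reader of methylated DNA, at 0.43 (-0.44 and 0.27 without DMSO replicate 2). Genes of nucleoside uptake and metabolism had a median of 0.22 with 14 of 15 positive (adjusted p = 0.0515), with RRM2B, a ribonucleotide reductase subunit gene, at 0.35 and CDA, cytidine deaminase, at 0.51 (0.25 without DMSO replicate 2 and 0.76 without DMSO replicate 1). Of these 2 lists, no member changed over all genes or adjusted over the list alone. Without DMSO replicate 2 the nucleoside list passed (median 0.14, adjusted p = 0.00619), and without DMSO replicate 1 it did not (0.21, adjusted p = 0.371). The DNA methylation list had medians of -0.04 without DMSO replicate 1 and -0.18 without DMSO replicate 2.

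Germline genes, often held silent by DNA methylation, were examined next, with interferon response, antigen presentation and imprinted genes. Of the 53 genes of the cancer-testis and germline list, 19 were in the table, which held no gene at 0 in every library. The 2 that passed the filter were TDRD9 with a log2 fold change of -0.24 and CTAG2 with 0.33 (0.16 without DMSO replicate 1, 0.51 without DMSO replicate 2). Neither changed over all genes or adjusted over the list alone. Of the 17 below the filter, 6 had both guadecitabine libraries above both DMSO libraries and 0 the reverse, at low levels. Chance gives 33.3% for the directions together only where the groups can separate. Genes with a value above 0 in 1 library alone, such as BRDT and TEX15, could not separate. The chance share over all 17 is thus lower, and 6 of 17 was not tested against it. Genes at 0 in both DMSO libraries could not be lower. By the same count, endothelial genes below the filter had 4 of 9 higher and 1 lower. Histone genes had 7 of 41 higher and 3 lower, and zinc finger genes 6 of 67 higher and 16 lower. The count therefore does not show a rise particular to germline genes. Among the 6 germline genes, chosen after their values were seen, GTSF1 was listed at 0 in both DMSO libraries and at 0.261 and 0.207 RPKM in guadecitabine. DAZL read 0.148 and 0.0330 against 0.291 and 0.286 RPKM. Interferon response genes had a median of -0.02 over 40 tested members (adjusted p = 0.251), with IFI27 at 0.67 and XAF1 at -0.75. Antigen presentation genes had a median of 0.13 (adjusted p = 0.520), with HLA-DPB1 at 0.84 and HLA-DMA at 0.80 (0.49 without DMSO replicate 2), in a family whose close copies can share reads. Imprinted genes had a median of 0.21 (adjusted p = 0.372), with 15 of 22 lowest in DMSO replicate 2. Without that library the median was 0.02 for imprinted and -0.0042 for antigen presentation genes, and without DMSO replicate 1 it was 0.10 for interferon response genes. Among the imprinted genes the growth factor gene IGF2 was at 61.3 ± 31.6 RPKM in DMSO and 185 ± 20.6 RPKM in guadecitabine, a log2 fold change of 1.68, and MEST had -0.37. Of these 3 lists, no member changed over all genes or adjusted over the list alone.

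Zinc finger genes had a median of -0.09 with 124 of 395 positive (camera, adjusted p = 7.4e-06, and adjusted p = 0.890 with an estimated correlation), while the 2 members with the smallest p, ZNF423 at 0.62 and ZNF547 at 0.41, were higher. Their median was -0.15 after median-of-ratios scaling, -0.14 after TMM scaling and -0.06 without DMSO replicate 1, each past the threshold. HOX genes had a median of 0.05 with a test pointing down (adjusted p = 0.923), and the median turned to -0.02 after quantile and median-of-ratios scaling and to -0.01 after TMM scaling; HOXB3 had -0.42 and HOXA7 0.60 (0.39 without DMSO replicate 2). Clustered protocadherins, whose members share exons and reads, had a median of 0.14 (adjusted p = 0.135), -0.01 without DMSO replicate 2 and 0.28 without DMSO replicate 1, where the list passed (adjusted p = 0.0132), with PCDHGA8 at 0.15 and PCDHGB4 at 0.14 (0.0070 and 0.0088 without DMSO replicate 2, 0.29 and 0.27 without DMSO replicate 1). Replication-dependent histone genes had a median of 0.30 with 11 of 11 positive and lowest in DMSO replicate 2 (adjusted p = 0.0515). Another 41 histone genes were below the filter, so the list rests on few of its members. HIST1H1C had 0.85 and HIST2H2BE 0.57 (0.39 and 0.25 without DMSO replicate 2, 1.30 and 0.89 without DMSO replicate 1). The histone list passed after quantile (adjusted p = 0.0188), median-of-ratios (0.0248) and TMM scaling (0.0252), without DMSO replicate 1 (0.58, 0.00647) and without guadecitabine replicate 2 (0.37, 0.0179). Without DMSO replicate 2 the histone median was 0.04 (adjusted p = 0.717). Ribosomal protein genes had a median of 0.17 with 75 of 75 positive (camera, adjusted p = 3.4e-05, and adjusted p = 0.890 with an estimated correlation), led by RPS26 at 0.58 and RPL39L at 0.51 (0.26 without DMSO replicate 2), and 66 were lowest in DMSO replicate 2. The ribosomal call ended after quantile normalization (0.03, adjusted p = 0.254) and without guadecitabine replicate 1 (0.12, adjusted p = 0.0797), and the median was 0.08 without DMSO replicate 2, 0.10 after median-of-ratios scaling and 0.10 after TMM scaling. In these 5 lists no member changed over all genes or adjusted over the list alone. Camera with an estimated correlation and fry each called 0 of the 27 lists. At an unadjusted p under 0.05 fry counted 2 lists, nucleoside metabolism and oxidative stress, and camera with an estimated correlation counted 0.

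**Figure D3:**
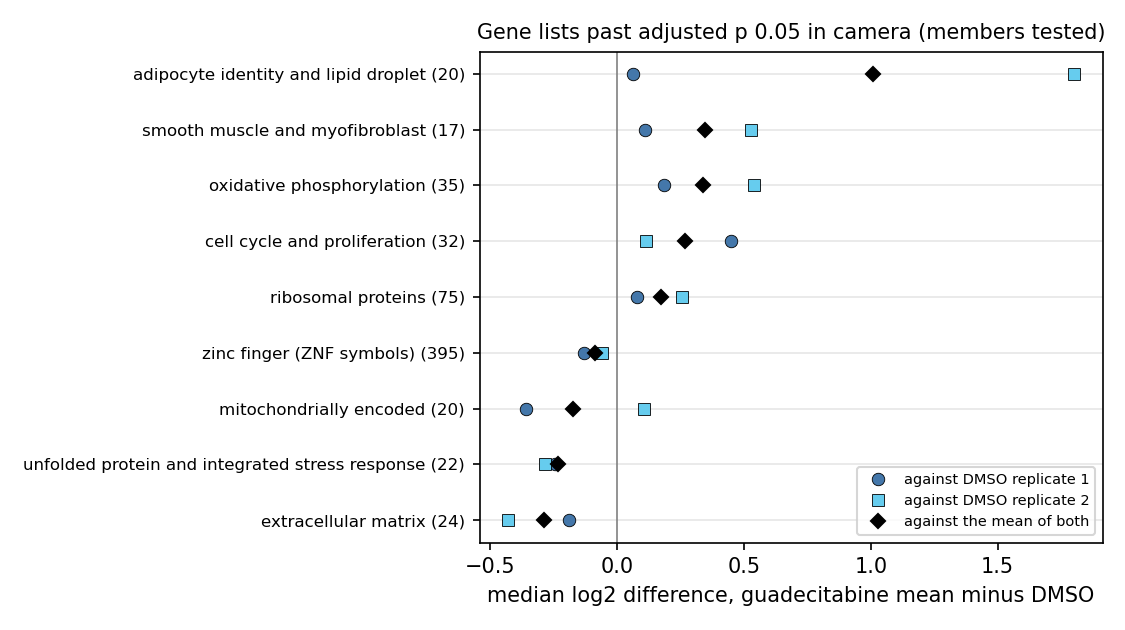
Median log2 difference between the guadecitabine mean and DMSO replicate 1 (circles), DMSO replicate 2 (squares) or the mean of both (diamonds) for the 9 lists past an adjusted p of 0.05 in camera with the preset correlation, with the tested members in parentheses. The adipocyte list spans 0.06 to 1.80 between the DMSO libraries, and the mitochondrially encoded list lies at -0.36 against DMSO replicate 1 and at 0.10 against DMSO replicate 2.

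By the rule for genes near 0, 1 gene was switched on with guadecitabine and 1 off, and the other 2 splits of the libraries into pairs gave 0 and 0. ECSCR (ENSG00000249751.3, chromosome 5 from 139448556 to 139462743), an endothelial surface protein gene whose symbol is on several lines of the table, was listed at 0 in both DMSO libraries and at 1.48 and 1.03 RPKM in guadecitabine. These values are those of 1 line, and do not show whether the gene as a whole was silent in DMSO. MIR922 (chromosome 3 from 197674496 to 197674576), a microRNA gene much shorter than an mRNA, read 1.21 and 1.88 RPKM in DMSO and was listed at 0 in both guadecitabine libraries. For 1 kb of exons, 1 read was worth 0.0484 and 0.0376 RPKM in DMSO replicates 1 and 2. In so short a gene the DMSO values of MIR922 amount to a few reads, too few to show a loss of expression. ECSCR and MIR922 were named after their values were seen.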

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

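Of the tests in this part, removal of the length trend in both forms and the quantile and TMM scalings of gene lists were chosen after the result was seen. No gene passed in either direction under either other pseudocount, either other filter, quantile, median-of-ratios or TMM scaling, or the other variance models. With the replicate number as a block, 25 genes were higher and 6 lower; the numbers share only a number (correlation of deviations 0.113), so this block has no stated pairing behind it. With the block the cholesterol and histone lists also passed (adjusted p = 0.0189 and 0.0160). With the length trend removed, 2 genes, ATOH8 and SUSD2, were higher with either length lookup. Leaving out 1 library gave 0 to 3466 higher and 0 to 876 lower genes, 3466 and 876 without DMSO replicate 1, 295 and 245 without DMSO replicate 2, and 0 without either guadecitabine library; each such fit assumes that the lone library varies like the other group. Of the gene lists, 9 passed with the preset correlation, 0 with an estimated correlation and 0 with fry. An estimated correlation allows for genes that vary together, and fry also asks a different question (against no change). The p also rose where the estimated correlation was below the preset 0.01. For nucleoside metabolism (-0.0073) the unadjusted camera p went from 0.0202 to 0.131. More than the correlation thus differed between the camera runs, and what ended the calls there or in fry was not tested. Switched on or off numbered 9 and 3 with 0.5 RPKM asked for in place of 1, which is the looser rule, and 3 to 8 and 3 to 12 with a library left out. DNMT1 had 0.016 with the length trend removed and -0.19 to 0.13 with a library left out. Test direction turned for HOX genes with fry (median 0.054) and quantile scaling (-0.017) and without DMSO replicate 1 or guadecitabine replicate 2, with leave-one-out medians of -0.11 to 0.22. It turned for p53 targets with quantile scaling (-0.020) and the length trend removed (0.036, or 0.037 by exact gene ID) and without DMSO replicate 1, with leave-one-out medians of 0.011 to 0.068. It turned for inflammatory genes with the replicate block (0.19) and the length trend removed (0.041, or 0.035 by exact gene ID) and without DMSO replicate 1 or guadecitabine replicate 2, with leave-one-out medians of 0.12 to 0.17. Leave-one-out alone turned the test direction, though not always the sign of the median, for fatty acid (-0.17 to 0.51), cholesterol (-0.14 to 0.66), beige (-0.14 to 0.50), preadipocyte (0.094 to 0.17), cell cycle (0.11 to 0.45) and protocadherin genes (-0.012 to 0.28). Apart from fewer samples and the stated rules, the cause was not tested. The planned edgeR and DESeq2 fits on reads were not run, because whole reads could not be recovered for every gene and the deposited unit is RPKM. In the simulation 38.4% of 2-fold changes were recovered, so smaller changes would mostly be missed at this spread.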

Other observations

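Targets of bone morphogenetic protein (BMP) signalling stood together on the higher side. Of such genes not seen before the test, all 8 tested were positive, and 5 rose adjusted over the list alone, against 0 over all genes. Another 2, MSX2 and HEY1, were below the filter. Beside ID1 and ATOH8, which had been seen, stood ID3, a helix-loop-helix protein like ID1, at 51.2 and 78.3 RPKM in DMSO and 244 and 288 RPKM in guadecitabine, a log2 fold change of 2.06 with a standard error of 0.23. The BMP antagonist gene NOG had 1.65, the signal transducer gene SMAD9 1.21, and the inhibitory SMAD6 and SMAD7 1.11 and 0.56. ID4 had 0.64, BAMBI 0.43, ID2 0.44 and MSX1 0.07, and these members were named after the list was seen.

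Of 17 epithelial genes in the table not looked at beforehand, 10 were tested. All 10 were positive with a median of 0.48, and 3 rose adjusted over the list alone, against 0 over all genes. A gene near the floor in DMSO can pass the filter through the guadecitabine libraries, which favours positive members. Below the filter were 7 genes, EPCAM, CLDN4, ELF3 and KRT5 among them. Of these 7, 1 had both guadecitabine libraries above both DMSO libraries and 1 the reverse. KRT7, a keratin of simple epithelia, was at 455 and 309 RPKM in DMSO and 911 and 750 RPKM in guadecitabine, a log2 fold change of 1.14. SFN had 1.27 and KRT16 0.84, both near the floor in DMSO, while DSP, the desmosomal gene desmoplakin, had 0.11.

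Of the tests in this part, those of depth and of a lower share of differentiated cells were chosen after the result was seen, as were the lists of BMP targets and of epithelial genes and the removal of the length trend in both forms.

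A candidate explanation for the higher ID1, ID3 and ATOH8 is a wider rise of BMP and SMAD target genes. The 8 tested targets not seen before the test had a median of 0.60, all positive (camera, adjusted p = 1.7e-05 over the 3 added lists). With an estimated correlation the adjusted p was 0.110, so the rise is not settled, while fry, which tests against no change, gave 0.0468. Against DMSO replicate 1 alone their median was 0.54 and against DMSO replicate 2 alone 0.76. For the higher KRT8, KRT14 and CD24, a wider rise of epithelial genes was tested in the same way, with the median of 0.48 above. Its adjusted p was 4.0e-04 with camera, 0.0990 with an estimated correlation and 0.00396 with fry. Both wider rises remain hypotheses from these 4 libraries.

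DMSO replicate 2 was lower than DMSO replicate 1 in all 20 adipocyte genes. Lower depth is argued against by its scaling total, 26.6 M reads, the highest of the 4 libraries. A scaling offset from a few abundant genes is argued against by the median difference after median-of-ratios scaling, -1.51, close to the -1.62 before it. A lower share of differentiated cells in DMSO replicate 2 may have contributed, and could not be decided. Extracellular matrix genes were higher there by a median of 0.34, but preadipocyte genes had -0.18, with members on both sides. The labels give no difference between the DMSO libraries beyond the replicate number.

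A transcript length trend between the libraries might place ribosomal protein and oxidative phosphorylation genes higher and zinc finger genes lower. With the trend removed, 3 of the 3 lists kept their sign, a median over 0.05 from 0 and a camera call, the medians going from 0.34 to 0.26 for oxidative phosphorylation, from -0.09 to -0.14 for zinc finger genes and from 0.17 to 0.06 for ribosomal proteins. For oxidative phosphorylation and zinc finger genes this held with either length lookup and argues against the trend as the whole cause, but the ribosomal call depended on the lookup. Lengths were first matched by exact gene ID, which covered 70.7% of ribosomal genes, under the 80% asked for, and gave 0.06 with an adjusted p of 0.0634; matching IDs without the version, done after that was seen, gave 0.0223. The same step moved the median of all genes from 0.05 to -0.0042, and median-of-ratios scaling alone gave 0.10 for ribosomal proteins and 0.27 for oxidative phosphorylation, so part of each fall goes with that general shift and not with length.

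An excess of genes switched on over genes switched off was looked for against the other splits of the libraries, and the difference was 0, with 1 gene each way, too few to decide anything. With 0.5 RPKM asked for in place of 1 there were 9 on and 3 off, which was not compared with the other splits. For the genes with an unadjusted p under 0.05, the real split gave 1654 and the highest of the 2 other splits 357, and 3 splits are too few for a share under 0.05.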
